A study of Mus musculus with 22 samples.

How the data were processed

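Whole-brain total RNA of naive adult male mice of the inbred strains C57BL/6J (B6) and DBA/2J (D2) was measured on the Affymetrix Mouse Exon 1.0 ST array, which carries probesets along the exons of each gene. Per the labels, each array held the RNA of 1 mouse. RNA was extracted with TRIzol, purified with RNeasy, depleted of ribosomal RNA, amplified and biotin-labelled. The labels state that 24 arrays were hybridised and that the authors left out 2 that a different scanner had read. The 22 arrays analysed here are those of 10 B6 and 12 D2 mice, so p-values measure the spread between mice.

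The authors deposited log2 expression values, made with RMA, affy 1.12.2 and R 2.6.0 per the submitters' processing notes. RMA corrects the background, equalizes the distributions of the arrays by quantiles and fits 1 value per probeset. Which of RMA's options were used, and the probeset definition, is not given in the sources used here. The table held 1201338 probesets, of which 10932 were empty on all arrays and were left out. The remaining values ranged from -0.90 to 12.98, and the medians of single arrays from 1.41 to 1.51. An array has no read depth, so the number of arrays limits the precision.

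GEO's platform annotation listed 1 gene symbol for 311384 probesets, several for 6385 and none for 883569, and these last are unnamed here. No gene was named from a probeset with several symbols. Of the 22276 platform symbols, 17991 were current in the mouse gene table used for names (GRCm38.p6), 3990 were updated through a synonym with 1 current symbol and 295 were kept as given. No coordinates are printed, since no build is named in the sources used here. That gene table served only for names and for the order of neighbouring genes. The array was designed on reference sequence of B6, so a D2 variant under a probe lowers the D2 signal without any change of the transcript. No variant table was used here.

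Values were analysed in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, D2 minus B6, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05). Probesets were kept where their mean over the 22 arrays was at or above the median of all probeset means, a log2 value of 1.44. This left 595203 probesets. A gene's value was the median, on each array, of its kept probesets with 1 symbol, for the 16016 genes with at least 3 such probesets (236114 probesets, median 12 per gene). Exon usage was tested on the splicing index, the log2 value of a probeset minus its gene's value on the same array. A probeset was called at an adjusted p under 0.05 and an index difference of at least 0.5. The index of a probeset that is always its gene's median is 0 on every array, and limma offset such variances from 0. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The share of list genes with an exon usage call was set against that of all other genes tested by Fisher's exact test, two-sided. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Figures were drawn with matplotlib 3.10.9.

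The rule for named genes was fixed before the data were examined. It took the 12 genes highest and the 12 lowest in D2 among called genes whose B6 and D2 values did not overlap. For exon usage it took the 12 probesets with the highest and the 12 with the lowest index difference, each gene once, with index values that did not overlap, and the 12 genes with the most called probesets. For each gene list it took up to 4 called members with the largest difference, or up to 2 others where no member was called, and every measured gene with a textbook strain variant. The 37 lists were fixed at the same time and held 665 genes, of which 582 were measured. They covered brain cell types (pan-neuronal, glutamatergic, GABAergic, striatal and cerebellar neurons, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia and macrophages, endothelial cells, pericytes and meningeal fibroblasts, ependyma and choroid plexus), other tissues (pituitary, red blood cells), receptor and channel families, splicing regulators, neuronal genes with textbook alternative exons, metabolic and stress pathways, immediate early genes, the circadian clock, the lysosome and textbook strain variants.

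The same functions were tested on simulated data, drawn from the real means and spreads with known changes. For the D2 against B6 gene test over 16016 genes, 8% of 50 genes changed by 0.25 (log2), 64% of those changed by 0.5, and all of those changed by 1 or by 2 were recovered, and 12 of 148 calls were false. For the exon usage test over 236114 probesets, 0% of those changed by 0.25, 16% of those changed by 0.5, 60% of those changed by 1 and 94% of those changed by 2 were recovered, and 13 of 98 calls were false. In the test of gene lists over 16016 genes, both of 2 lists of 20 genes shifted by 0.3 were called and 0 of the 18 other lists. The simulated genes varied independently of each other and the lists were random. The simulation therefore does not show how often real lists, whose genes may vary together, are called falsely.

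Alternatives fixed before the data were examined were no filter, a filter at the 75th percentile, a repeated quantile normalization, array number as covariate, the letter in the submitters' file label as block, arrays of each letter alone, eBayes with trend and robust settings, and leaving out each mouse in turn. Further ones were centring each array on its median, the mean in place of the median over probesets, at least 5 probesets per gene, minimum differences, an index against the mean of the other probesets, and limma's diffSplice. What the letter in the file label stands for is not given in the sources used here. It was B for 2 B6 and 2 D2 arrays and A for the other 18. Replicate numbers were not shared between the strains, so no array was paired.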

Results

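Gene and exon expression was compared between whole brains of 10 B6 and 12 D2 mice, strains that are widely used in mouse genetics and behaviour research and that differ at many loci. The title of the series names alternative splicing as the subject of the comparison. Over the kept probesets, arrays of the same strain correlated with a median r of 0.945 across probesets (range 0.914 to 0.960) and arrays of different strains with a median r of 0.935. These values are across probesets, which are not independent replicates. The first principal component of the gene values held 24.3% of the variance and had a mean score of -16.3 in B6 and 13.6 in D2. The second held 13.0% and set the 4 arrays with file letter B (mean -24.7, highest -18.9) apart from the 18 with letter A (mean 5.48, lowest -9.88). The letter was present in both strains. The median over all probesets of an array was 1.44 ± 0.018 in B6 (SD, n = 10) and 1.47 ± 0.018 in D2 (SD, n = 12; permutation test, two-sided, p = 0.00013), and that over annotated probesets was 4.04 ± 0.084 in B6 and 3.97 ± 0.084 in D2 (permutation p = 0.0658). In B6 the array with the lowest score on the first component (replicate 5, -38.1) had the lowest median (1.41). The B6 array with the highest score (replicate 11, 1.37) had the highest median (1.47). In D2 replicate 19 had the highest score (39.8) and the highest median (1.51), but the lowest score (replicate 23) did not go with the lowest median. The first component can therefore not be read as strain alone.

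**Figure D1:**
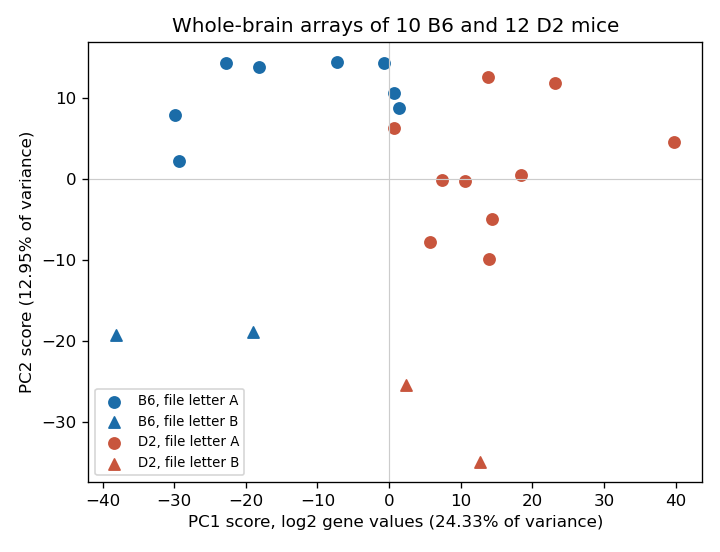
Scores of the 22 arrays on the first (x) and second (y) principal components of the log2 gene values, by strain (colour) and file letter (shape). B6 scores on the first component ran from -38.1 to 1.37 and D2 scores from 0.72 to 39.8, and the 4 arrays with letter B lie at or below -18.9 on the second.

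The largest strain differences were of single genes. Stab2, a scavenger receptor for hyaluronan, was 22.7-fold higher in D2, at 6.06 ± 0.29 (log2, SD, n = 12) against 1.55 ± 0.11 in B6 (SD, n = 10; limma adjusted p = 1.9e-22). Sfi1, a centrin-binding protein of the centrosome, was 4.86-fold higher in D2 (3.90 ± 0.18 in B6, 6.18 ± 0.14 in D2). The other genes with the largest increases were AI506816, Pisd-ps3, Mrpl20 of the mitochondrial ribosome (3.86-fold), AA465934, the tubulin-folding cofactor Tbcb (3.40-fold), Slfn8, Xaf1 (2.92-fold), Cfap54 and the tRNA deaminase subunit Adat2 (2.87-fold). H2-Ea, the class II gene that is silent in the H2 haplotype of B6, was at 1.23 ± 0.25 in B6 and 2.89 ± 0.39 in D2. The lowest in D2 was 1500004A13Rik, at 7.06 ± 0.15 in B6 and 1.93 ± 0.22 in D2, a difference of -5.13 ± 0.087 (SE). The carbohydrate kinase gene Fggy fell by 3.88 (5.14 ± 0.20 in B6, 1.26 ± 0.20 in D2), the myocilin gene Myoc by 3.19 and Pttg1, which encodes securin, by 2.31. Hbb-b1, a beta-globin gene with close paralogs, was 10.16 ± 0.18 in B6 and 6.04 ± 0.72 in D2 over 3 probesets. A830036E02Rik, 4930578G10Rik, Zfp874a, Gm9866, 4933409K07Rik, 2610507I01Rik and AA388235 complete the 12 lowest, with differences from -3.73 to -2.38. Several of these genes lie near or below the filter level of 1.44 in the strain with less signal, where folds are compressed by the background. Fggy (1.26), Myoc (0.83) and A830036E02Rik (1.26) lay below it in D2 and H2-Ea (1.23) in B6. The size and order of such differences are therefore not informative.

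**Figure D2:**
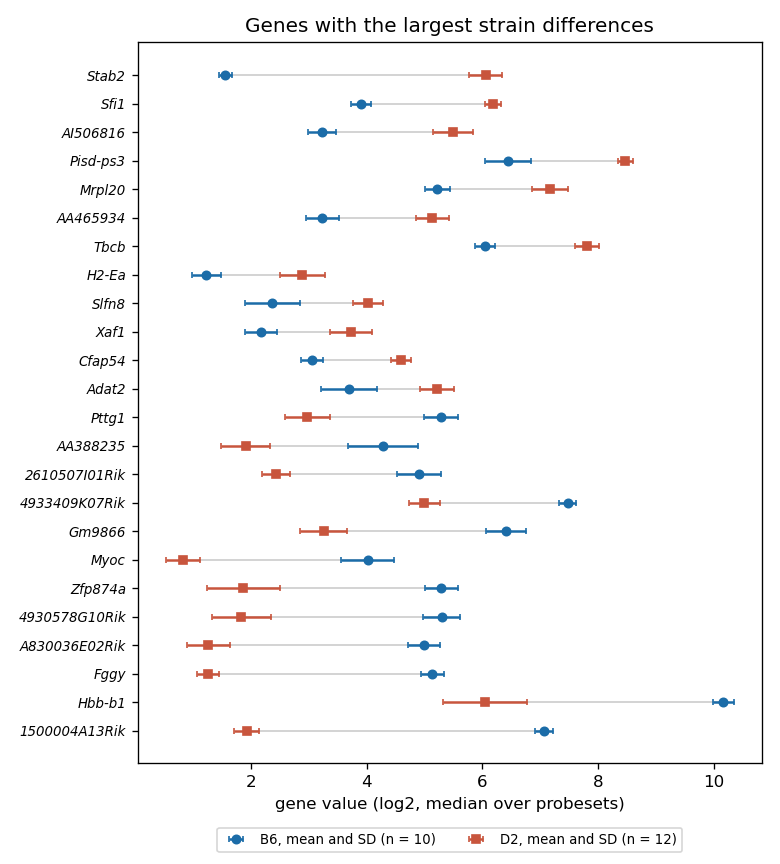
Mean and SD of the gene value (x, log2) in 10 B6 and 12 D2 mice for the 12 genes highest and the 12 lowest in D2 (y). The values of the strains do not overlap for any gene drawn, from Stab2 (4.50 higher in D2) to 1500004A13Rik (5.13 lower, difference -5.13).

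In all, 1735 of the 16016 genes tested differed between the strains (10.8%), 412 higher and 1323 lower in D2, so that 76.3% of the calls were lower in D2 (95% interval 74.2% to 78.2%). The direction of the count depended on the scaling. With each array centred on the median of its genes, 1779 genes were called, 1168 of them shared with the 1735, of which 1023 were higher and 756 lower (42.5% lower), and the median difference of all genes moved from -0.053 to 0.046. With the array median as covariate, added after the data were seen, 495 genes were called, 266 higher and 229 lower, of which 363 were shared with the 1735, and with the mean over probesets 2718 were called, 786 higher and 1932 lower. Of the 1735 genes, 640 differed by at least 0.5 (169 higher, 471 lower) and 109 by at least 1 (33 higher, 76 lower). The B6 and D2 values did not overlap for 189 called genes (49 higher, 140 lower), against 0.000309% of genes by chance. With the file letter as block 2127 genes were called (76.6% lower), with the letter A arrays alone 1350 (73.3% lower) and with the 4 letter B arrays alone 75 (80.0% lower). At the level of probesets, 23265 of 595203 were called, 9947 higher and 13318 lower in D2 (57.2% lower). With each array centred on its median over all probesets, 8141 were higher and 15880 lower (66.1% lower), and with the array median as covariate 6445 were higher and 4538 lower (41.3% lower). Among kept probesets with 1 gene 68.7% of the 9802 calls were lower in D2, and among those without a single gene 48.9% of 13463.

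Genes with textbook strain variants served to check the strain labels. Glo1, which lies in a duplicated segment in D2, was 1.82-fold higher in D2 (6.41 ± 0.11 in B6, 7.28 ± 0.24 in D2), and Alad, also duplicated in D2, was 2.34-fold higher (5.98 ± 0.22 and 7.21 ± 0.25). Gabra2, a GABA-A receptor subunit with an intronic deletion in B6 that lowers its expression, was 2.11-fold higher in D2 (6.01 ± 0.24 and 7.09 ± 0.14). Gpnmb, which carries a nonsense allele in D2, fell by 1.02 in D2 (2.87 ± 0.16 and 1.85 ± 0.31). Mpdz fell by 0.60, and the complement gene Hc was 0.58 higher in D2 over 3 of its 43 probesets, at levels near the filter. Nnt, from which B6 lacks several internal exons, was 1.25-fold higher in D2 (adjusted p = 0.0363). All of its 27 probesets were kept. None was called with a higher index in D2, and 3 were called with a lower one (-1.59, -1.21 and -1.16). These values do not show the deletion. They cannot decide on it either, since an array designed on B6 sequence may hold no probeset in the deleted exons. Whether any of the 27 lies there is not known here. Cox7a2l (0.073), Kcnj9 (0.052), Ahr (-0.065), Tyrp1 (-0.081), Cdh23 (0.12), Fscn2 (0.17) and Myo5a (-0.18) were not called. Klrd1 and Taar1 had no kept probeset. A direction had been set in advance only for Nnt, Gpnmb and Klrd1, so Gpnmb was the only clear check among those planned. As a list, 5 of the 14 measured genes rose, 2 fell and 7 were not called (5 and 3 adjusted over the list alone), with a camera adjusted p of 0.0233 (adjusted p = 0.0922 with an estimated correlation). This list was chosen for genes known to differ between the strains.

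Of 12 measured markers of ependyma and choroid plexus, 3 fell and 9 were not called (0 higher and 5 lower adjusted over the list alone), with a camera adjusted p of 0.00872 (adjusted p = 0.0922 with an estimated correlation). Foxj1, the regulator of motile cilia, fell by 0.65, the folate receptor Folr1 by 0.61 and Otx2 by 0.49. Of the red blood cell list only 3 genes were measured. Hbb-b1 and the erythroid heme enzyme Alas2 (-0.90 ± 0.17, SE) fell and Slc4a1 was not called (0.012 ± 0.12), with a camera adjusted p of 0.00872 (adjusted p = 0.0922 with an estimated correlation). Of 14 immediate early genes, which neurons switch on with activity, 4 fell and 10 were not called (0 and 5 adjusted over the list alone): Ier2 (-0.81), Arc (-0.66), Egr3 (-0.61) and Egr4 (-0.58, but 0.13 with the filter at the 75th percentile), with a camera adjusted p of 0.0496 (adjusted p = 0.84 with an estimated correlation). Of 14 heat shock and chaperone genes, 5 fell and 9 were not called (0 and 6 adjusted over the list alone), led by Hspb1 (-0.93), Dnajb1 (-0.58), Hspa5 (-0.43) and Hsph1 (-0.40), with a camera adjusted p of 0.0426 (adjusted p = 0.84 with an estimated correlation). Without the 3 arrays that correlated least with their strain (D2 replicates 13, 14 and 19, chosen after the data were seen), the choroid plexus and red blood cell lists were called and the immediate early (adjusted p = 0.0607), heat shock (0.0667) and strain variant (0.0728) lists were not. The same 3 lists were not called with the array median as covariate (0.163, 0.676 and 0.447), and the immediate early genes were not with the mean over probesets (0.104). Of 100 splits of the arrays into groups of the same sizes, the real one included, 7 gave at least as many called lists as the 4 that were lower in D2, with the strain variant list left out.

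The other 32 lists were not called by camera (adjusted p from 0.0791 to 0.985). Some were called under an alternative: astrocytes and oligodendrocytes and myelin without the filter (both lower in D2, adjusted p = 0.0312), cerebellar neurons (0.0243) and endothelial cells (0.0347) with the mean over probesets (both lower), and GABA-A receptor subunits with the array median as covariate (higher, 0.0147). Fry, which tests whether a list moves one way without setting it against other genes, called 15 lists, 14 lower and 1 higher in D2. Calls of single genes depended on the scaling too. The genes with the largest differences and the called list members were 102 together. Of these, 24 lost their call with each array centred on its gene median and 62 with the array median as covariate. Of 11 astrocyte genes, 4 fell and Gja1 rose by 0.28 (1 and 5 adjusted over the list alone). Gfap fell by 0.80, though 7 of its probesets had a higher index with no called change of their own level, Aldh1l1 by 0.40, Gjb6 by 0.40 and Aldoc by 0.25. Gja1 was at -0.11 with all probesets used. Of 11 oligodendrocyte and myelin genes, Mobp (-0.78), Mal (-0.51) and Ermn (-0.49) fell and 8 were not called (0 and 4 adjusted over the list alone). Of 14 microglia and macrophage genes, C1qb (-0.90), Cd68 (-0.49) and Mrc1 (-0.32) fell. Of 11 endothelial genes, Slco1a4 (-0.41) and Pecam1 (-0.33) fell, and of 11 genes of pericytes and meningeal fibroblasts Acta2 (-0.70) did (1 and 3 adjusted over the list alone). Of 10 genes of cerebellar neurons, Car8 (-0.52) and Cbln3 (-0.40) fell (0 and 3 adjusted over the list alone). Map2 (-0.38) was the only called one of 11 pan-neuronal genes, Calb2 (-0.31) of 10 GABAergic and Drd2 (-0.25) of 10 striatal genes. None of 7 glutamatergic genes (Slc17a6 at -0.28, Neurod1 at -0.22), of 8 genes of oligodendrocyte precursors (Olig1 at -0.22, Bmp4 at -0.13) or of 4 pituitary genes (Gh at 0.69 ± 0.89, SE, Pomc at 0.56 ± 0.47) was called.

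Of 12 GABA-A receptor subunits, Gabra2 rose and Gabra5 fell by 0.33 (0.021 with the array median as covariate). Grin2b (-0.29) was the called one of 16 ionotropic glutamate receptor genes, and none of 6 metabotropic ones was called (Grm2 at 0.23, Grm7 at -0.07). Of 22 genes of the monoamine systems, Maob (-0.58), the noradrenaline-producing enzyme gene Dbh (-0.46) and Drd2 fell (0 and 7 adjusted over the list alone). Of 12 opioid and cannabinoid genes, Oprl1 fell by 0.33. Of 17 acetylcholine receptor and synthesis genes, Chrna3 fell by 0.55 and Chrnb4 rose by 0.49. Of 30 potassium channel genes, the glial channel Kcnj10 rose by 0.66 and Kcnb2 (-0.35) and Kcnj4 (-0.31) fell. Cacnb1 (-0.29) was the called one of 24 calcium and sodium channel genes, Stx1a (-0.23) of 25 synaptic vesicle release genes (0 adjusted over the list alone), Celf4 (-0.41) of 41 splicing regulators and Drd2 of 52 neuronal genes with textbook alternative exons (0 adjusted over the list alone).

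Of 19 glutathione system genes, Glo1 and Gsr (0.64) were among 3 that rose, and Gsto1 (-0.61) and Gclm (-0.46) among 4 that fell (4 and 5 adjusted over the list alone). Of 12 genes of alcohol and aldehyde metabolism, Aldh7a1 (-0.95) and Aldh9a1 (-0.63) fell (0 and 3 adjusted over the list alone). Of 17 genes of antigen presentation, H2-Ea (1.66) and H2-Q10 (0.79) rose and H2-Ab1 (-1.04), H2-K1 (-0.68) and B2m fell (4 and 4 adjusted over the list alone). The H2 genes among these differ in sequence between the strains and have close paralogs. Of 15 interferon-stimulated genes, Xaf1 rose and Bst2 (-0.38), Irf9 (-0.28) and Stat2 (-0.22, but 0.045 on the letter B arrays alone) fell. Of 28 cytosolic ribosomal protein genes, which have many pseudogenes, Rps15 (0.57), Rpl23 (0.55) and Rps20 (0.50) rose and Rps3 (-1.82) and Rpl15 fell. With the filter at the 75th percentile Rps3 was at 0.26 and Rpl23 at -0.14, and with the mean over probesets Rps3 was at -1.35 and Rpl23 at -0.026. Of 35 oxidative phosphorylation genes, Cox6a1 (1.05) and Sdhc (0.75) rose, and Cox6a1 was at -0.037 with the mean over probesets. Of 17 cholesterol synthesis genes, Cyp51 (-0.47, but 0.087 with the array median as covariate) and Hsd17b7 (-0.30) fell. Of 16 circadian clock genes, Dbp rose by 0.45. Of 20 lysosomal genes, Gpnmb (-1.02) and Grn (-0.27) fell. For lists without such a note, the counts adjusted over the list alone equalled those over all genes. The median and the mean of a list differed in sign for GABA-A receptor subunits, metabotropic glutamate receptors, oxidative phosphorylation, oligodendrocyte precursors and cytosolic ribosomal proteins. Camera, which sets a list against the other genes, gave an upward direction without a call where both lay below 0 for ionotropic glutamate receptors, the opioid and cannabinoid system, synaptic vesicle release, neuronal genes with textbook alternative exons, the glutathione system, antigen presentation and the circadian clock.

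**Figure D3:**
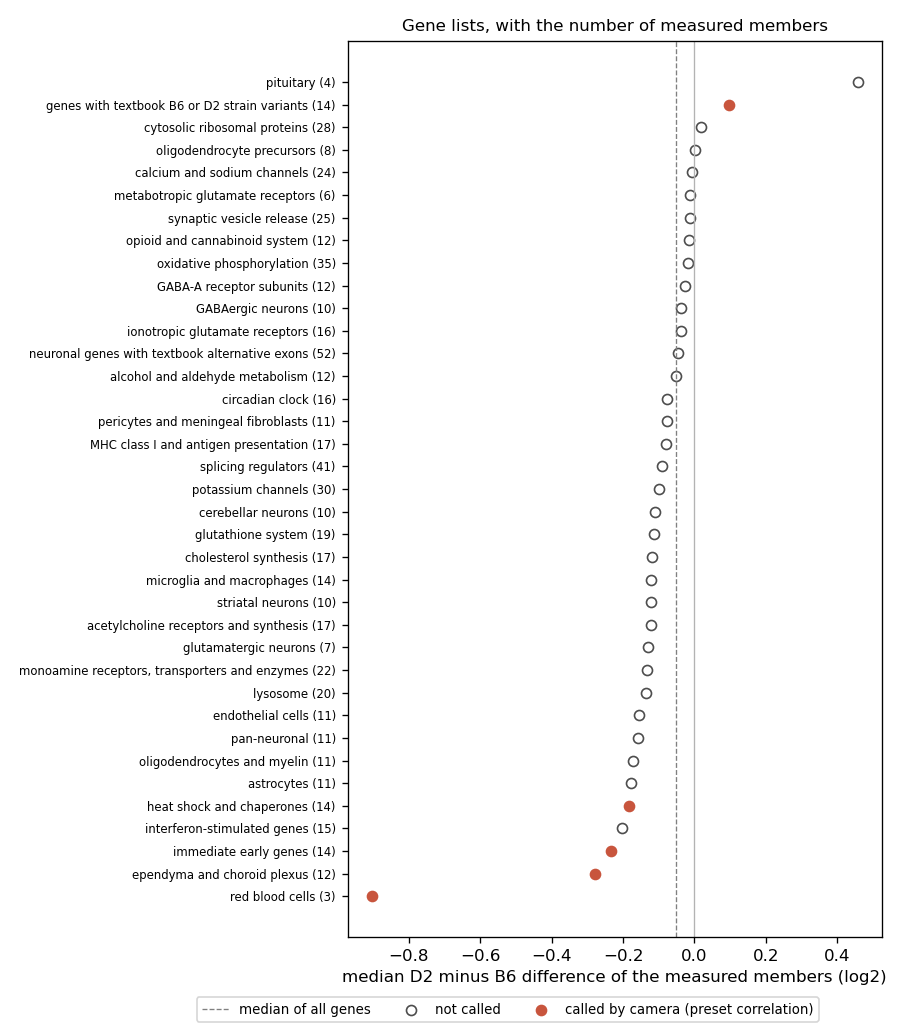
Median D2 minus B6 difference (x, log2) of the measured members of each of the 37 gene lists (y, number of measured members in parentheses). Filled points are the 5 lists called by camera with the preset correlation, and the dashed line is the median of all genes (-0.053). The red blood cell list lies lowest (-0.90).

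The splicing index was called different between the strains (an exon usage call) for 3929 probesets of 2222 genes (13.9% of the genes tested). Such a call need not be a difference in splicing, since a D2 variant under the probes can also lower the index. The largest falls of the index in D2 were larger than the change of the gene as a whole. The probeset of Metap2, a methionine aminopeptidase, with the largest difference fell by 6.20 on the index, and its own level was 6.12 ± 0.56 in B6 (SD, n = 10) and 0.042 ± 0.25 in D2 (SD, n = 12), while the gene value differed by 0.12. Arpp21 (-5.98), the Na,K-ATPase regulator Fxyd7 (-5.84), Ndrg3 (-5.65), Rere (-5.54), the receptor phosphatase gene Ptprj (-5.46), the pyruvate carboxylase gene Pcx (-5.42), Klhl20 (-5.28), Pcdhgb5 (-5.19), Ociad1 (-5.17), Tcp11l1 (-5.12) and Fmn2 (-4.92) followed. The D2 level of the probeset lay below the filter level of 1.44 in Metap2, Ndrg3, Klhl20, Pcdhgb5, Ptprj, Ociad1, Fxyd7 and Pcx, so these falls are limited by the background and their order is not informative. Of these genes Fxyd7 (-0.60), Pcdhgb5 (-0.50), Fmn2 (-0.49), Pcx (-0.44) and Klhl20 (-0.36) were also called at gene level. The largest rises in which the probeset's own level rose were in Zc3h11a (index difference 4.27, own level 2.98 ± 0.86 in B6 and 7.22 ± 0.27 in D2), the proteasome gene Psmb5 (4.15), H2-K2 (3.61), Tmem87a (3.23), the mitochondrial superoxide dismutase gene Sod2 (3.07), Wdr89 (3.04), the ubiquitin ligase gene Cblb (2.87) and Rhobtb2 (2.81). In B6 the probesets of Psmb5 (-0.085) and H2-K2 (0.41) lay below the filter level, which limits these rises in the same way. In 1500004A13Rik (4.28), Zfp874a (3.38), Myoc (3.02) and Hbb-b1 (2.74) the index rose while the probeset's own level did not rise, since the gene value had fallen by more. The 12 lowest and 12 highest probesets kept their call and direction under every alternative in which they were tested except the fit of the 4 arrays with letter B alone.

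Of the 3929 probesets, 2110 had a higher and 1819 a lower index in D2, so that 46.3% were lower (95% interval 44.7% to 47.9%). This direction was lost, with shares close to even, under 3 alternatives. These were diffSplice (50.9% of 6324 calls lower), leaving out the 3 arrays that correlated least with their strain (50.3% of 3344) and the array median as covariate (50.4% of 2118). It turned with a minimum difference of 1, where the share was 57.05% of 1341 calls, and with 2, where it was 76.3% of 262 calls. The own level of the probeset was called the same way for 868 of the calls higher in D2 (41.1%) and for 1407 of those lower in D2 (77.4%). Most genes, 1516, had a single called probeset, and 545 had at least 2 called in the same direction. Of the genes with an exon usage call, 716 were also called at gene level (32.2%, against 7.39% of the other genes). The index subtracts the gene value, so a change of that value alone shifts the index of probesets that do not follow it. This contrast is therefore partly built into the measure. A minimum of 2 probesets in the same direction left 545 genes and the array median as covariate 1358, and diffSplice called 3784.

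**Figure D4:**
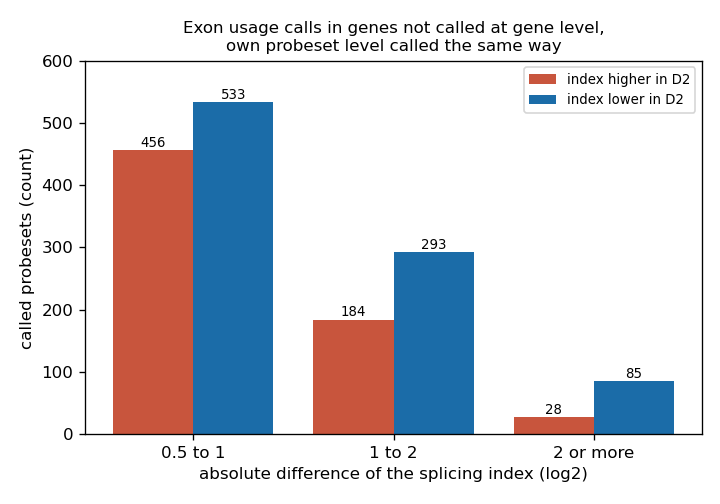
Number of exon usage calls (y) by absolute difference of the splicing index (x, log2), higher or lower in D2, in genes not called at gene level and with the probeset's own level called the same way. Calls lower in D2 made up 533 of 989 between 0.5 and 1 and 85 of 113 at 2 or more.

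The genes with the most called probesets were Stab2 (44 of 69) and Sfi1 (43 of 94), followed by Sgip1 (32 of 149), Noct (29 of 94), 5830417I10Rik (21 of 88), the myosin gene Myo7a (19 of 50), 1500004A13Rik (15 of 18), Ap3d1 (15 of 64), 4933409K07Rik, Armcx1, Dnah6 and Rec8. In Stab2 the own level of all 69 probesets was higher in D2, by 0.99 to 7.05. The gene value lay near the background in B6 for Stab2 (1.55) and in D2 for 1500004A13Rik (1.93), which limits the reading of their index differences as exon usage, though the 1500004A13Rik probeset with the largest difference was at 7.31 in B6 and 6.45 in D2. In Noct 28 of the called probesets were higher in D2 and 1 was lower, with a gene difference of -0.15 ± 0.093 (SE). In Ap3d1, a subunit of the adaptor complex of lysosome-related organelles, all 15 were higher in D2, by up to 3.76, with a gene difference of 0.011 ± 0.056.

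None of the 37 lists had a share of genes with an exon usage call that passed the adjustment (Fisher's exact test), and 2 had an unadjusted p under 0.05. Of 52 neuronal genes with textbook alternative exons, 15 had a call (28.8%, p = 0.00413, adjusted p = 0.0764), and of the 14 textbook strain genes 7 (50%, p = 0.00137, adjusted p = 0.0508). With the file letter as block, added after the data were seen, both passed (adjusted p = 0.0281 and 0.0139). Over the alternatives run, the adjusted p ranged from 0.0206 to 0.733 for the neuronal genes and from 0.00231 to 0.0191 for the strain genes. Alcohol and aldehyde metabolism passed with the array median as covariate (5 of 12 genes, 41.7%, adjusted p = 0.0256, up to 1 over the alternatives). Among the neuronal genes, with examples chosen after their values were seen, 1 probeset each of Ptprd (-2.90), Ncam1 (-2.21) and Gria1 (-1.39) had a lower index in D2. In Homer1 4 probesets were lower, by 0.74 to 1.37 (index differences -0.74 to -1.37), and 1 was higher by 0.66. The own level of that higher probeset was not called (0.57, limma adjusted p = 0.0582). Most Homer1 probesets had a lower own level in D2. Some were called lower without an index call (such as -0.44, limma adjusted p = 0.0149), so the fall was not confined to the 4 probesets.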

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

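The test of blood content as the whole cause of the Hbb-b1 difference, on all shared globin probesets, was chosen only after its result was seen. In 4 of 67 tested values 1 of the 10 B6 arrays stood apart from the rest, and chance alone flags about 1 in 20. The D2 group of 12 arrays was not tested in this way. For Xaf1, B6 replicate 8 was at 1.52 with the nearest array at 2.02 (gap over range 0.495). For 4930578G10Rik, B6 replicate 11 was at 6.06 with the nearest at 5.40 (0.584), and for Mpdz the same array was at 5.52 with the nearest at 5.78 (0.472). For the mean of the red blood cell list, B6 replicate 6 was at 5.21 with the nearest at 5.50 (0.519).

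The red blood cell list rests largely on Hbb-b1, which was 4.12 lower in D2 (difference -4.12 ± 0.21, SE). With less blood in D2 samples, all globin transcripts would fall alike. The 15 kept probesets listed for a pair of globin genes had a median difference of -0.49 (from -1.51 to -0.36), which argues against blood content as the whole cause. A bound of -1 was set in advance for the median difference of the 10 alpha-globin probesets. The median of their own differences was -0.50, above that bound. The difference of their median on each array was -0.91 (95% interval -1.16 to -0.65), which is not clear of it. That value depends on 1 probeset with a difference of -1.51 (10.7 in B6, 9.23 in D2). It lay above the middle of the 10 in B6 and below it in D2, which moved the array median further. The others differed by -0.36 to -0.61. The alpha-globin signal was lower in D2 (permutation test on the array medians, two-sided, p = 5e-05), but that p rests on the same array medians. Alas2 fell as well, while Slc4a1 was not called, so a smaller difference in blood content stays open. The differences of the 8 kept beta-globin probesets ranged over 3.68, in line with D2 sequence under the 2 bright Hbb-b1 probesets or with another D2 beta-globin haplotype, which these data do not separate.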

How the results depend on the processing

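Leaving out the 3 arrays least correlated with their strain, the array median as covariate, and the letter block for gene lists and for exon usage calls in lists were chosen after the data were seen, and the cause of each change below was not tested unless stated. Probeset, gene and exon usage counts stayed within 1.5 times under no filter, the 75th percentile filter, repeated quantile normalization, array number, letter block, letter A alone, and trend and robust settings. With each mouse left out, they ranged from 19171 to 25271 probesets, 1309 to 1945 genes, 3298 to 4483 exon usage probesets and 1878 to 2651 of their genes, and the share lower in D2 from 42.9% to 48.5%. With the 4 letter B arrays alone, fewer samples, 436 probesets, 75 genes, 0 exon usage probesets and 0 of their genes were called, so no share could be given. Similar counts did not mean the same calls. Of the 1553 genes called without filter 1224 were among the 1735, and of the 1583 at the 75th percentile 1022 were. For exon usage probesets, 3195 of 4351 without filter and 2010 of 2677 at the 75th percentile were among the 3929. A minimum difference of 0.5 left 640 genes, and the mean over probesets gave 2718. DiffSplice gave 6324 probesets and 3784 genes, an index difference of at least 1 gave 1341 and 819, and 2 probesets in the same direction gave 545 genes. The share of exon usage calls lower in D2 was 44.7% without filter, 48.3% at the 75th percentile, 48.8% against the mean of the other probesets, 50.9% with diffSplice, 44.3% without a minimum and 57.05% with a minimum of 1, 50.3% without the 3 arrays and 50.4% with the array median. That covariate, which is itself tied to strain, left 10983 probesets, 495 genes (363 of them shared with the 1735) and 2118 exon usage probesets of 1358 genes. Camera called 0 lists with an estimated correlation, fry 15, camera 2 without the 3 arrays and 3 with the array median. Exon usage calls passed in 1 list without filter, with a minimum of 1 and without the 3 arrays, in 2 with the letter block and in 3 with the array median. All 24 named exon probesets kept their direction. Of 102 named genes, 93 did, and of the 102, 24 lost their call with each array centred on its gene median, 62 with the array median and 81 on letter B arrays. Gja1 was at -0.11 without filter, Egr4 at 0.13, Rpl23 at -0.14 and Rps3 at 0.26 with the 75th percentile filter, Stat2 at 0.045 on letter B arrays, Cox6a1 at -0.037 and Rpl23 at -0.026 with the mean over probesets, and Cyp51 at 0.087, Gabra5 at 0.021 and Hspa4 at 0.0033 with the array median. Signal over background limits genes near the filter level.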

Other observations

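The tests of large exon usage calls lower in D2, of the own level of exon usage probesets in each direction, of centring, file letter and array median for the direction of gene calls, and of other splits of the arrays were chosen only after their results had been computed. Some genes had a wide spread between mice of a strain. The pituitary hormone gene Gh had a within-strain SD of 2.36 and Pomc of 1.24, and the olfactory mucosa genes Scgb1c1 (1.34), Cyp2g1 (1.04) and Omp (0.73) were also among the 40 most variable, against a median of 0.25 over all genes. These genes were chosen after their values were seen. The file letter, whose meaning is not given in the sources used here, was associated with 2374 genes with strain in the model, of which 735 were higher on the letter B arrays. Splicing regulators were higher with letter B (median 0.13, camera adjusted p = 0.000736) and the opioid and cannabinoid list was lower (median -0.31, adjusted p = 0.0466). The letter was called for 15 of 41 and 4 of 12 of their genes. Both lists were tested at the preset correlation only, and no strain list was called with an estimated one. Both strains held 2 letter B arrays.

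More genes were lower than higher in D2, and technical explanations may account for that excess. Blocking by file letter left 76.6% of the calls lower, and leaving out the 2135 probesets whose index was lower in D2, which by itself favours higher calls, left 73.7%, which argues against the letter and against sequence variants under identifiable probesets as the whole cause. Centring each array on the median of its genes gave 42.5%. Centring itself sets the balance of higher and lower calls, though (the median difference moved from -0.053 to 0.046), so this decides nothing. Repeating the quantile normalization over all probesets, which gives every array the same distribution, left 77.7% of 1730 calls lower (386 higher, 1344 lower). The median over all probesets was higher in D2 (1.475) than in B6 (1.437). These values argue against an offset shared by all probesets of an array. An offset of annotated probesets alone is neither shown nor excluded. With the array median as covariate the share was 46.3% of 495 calls, but that median is tied to strain, so this does not separate the array level from strain. A lower total of annotated transcripts in D2 brain is not excluded and was not tested.

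Exon usage calls may reflect D2 variants under probes designed on B6 sequence as well as splicing. Among calls of at least 2 in genes not called at gene level, with the probeset's own level called the same way, 75.2% of 113 were lower in D2 (95% interval 66.2% to 82.9%), against 53.9% between 0.5 and 1, as variants would give. Exons missing from D2 transcripts would give the same excess, as would an array without probes for exons used in D2 alone. For calls higher in D2 a variant cannot raise the probeset's own level, yet 41.1% had an own level called higher, which argues against variants for that part. Probesets that failed to follow a change of their gene would have no called difference of their own level, which held for 39.2% of all calls, for 19.4% of those lower in D2 and for 56.3% of those higher in D2, so this argues against that explanation for most lower calls and leaves it open for the higher ones, as strain differences in splicing stay open, untested by another method.

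Other splits of the 22 arrays into 10 and 12 were drawn, 100 with the real one. For probesets, genes, exon usage probesets and their genes, 1 of 100 splits, the real one, gave a count as large. The counts were 23265 against at most 94, 1735 against 10, 3929 against 676, and 2222 against 621. This argues against chance for these counts, though 100 splits cannot resolve a share under 1 in 100. For gene lists called by camera, 1 of 100, the real one, gave as many (5 against at most 4), but 48 of the 99 others called at least 1 list and 8 called 4. Without the list of strain variants, which was chosen for genes known to differ, the real count was 4, the highest other was 4 and 7 of 100 splits gave as many, so chance cannot be excluded for that number of lists. This test does not bear on single genes of these lists, of which Hbb-b1 in the red blood cell list differed by -4.12 with values of the strains apart (limma adjusted p = 6.5e-14). For exon usage calls in lists the real count was 0 and the highest other 1, and 100 of 100 splits reached the real count, which decides nothing. The share of exon usage calls lower in D2 could not be set against other splits, since 94 of the 99 others had no call, 4 had 1 and a single one had 676 (23.7% lower in its second group, which held 7 D2 arrays and 3 with letter B).

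A hypothesis was that strain haplotypes give runs of neighbouring called genes. In gene order, 14.8% of 1718 called genes were followed by a called gene, against 10.8% on average and 13.8% at most in 10000 shuffles, consistent with the hypothesis, though overlapping or duplicated neighbours could add to it. For exon usage calls the share was 20.7% (at most 16.4% in shuffles). The longest run held 6 genes, Npl, Rgs8, Rgs16, Rgsl1, Teddm2 and Glul, 5 of them lower in D2. A second hypothesis was that the lower Homer1 probesets mark an activity-dependent form that moves with the immediate early genes. Within strains the index of these 4 probesets and the mean of the 14 early genes had r = 0.338 in B6 (rho = 0.370, n = 10, permutation p = 0.328 and 0.295) and r = 0.21 in D2 (rho = -0.028, n = 12, permutation p = 0.523 and 0.941), with adjusted p of 0.523 for both r and of 0.589 and 0.941 for rho over the 2 relations. Without the 2 mice farthest from the median r was 0.418 and -0.345, and with letter A alone 0.269 (8 mice) and 0.174 (10 mice). The lower of the pair, 0.21, missed the bound of 0.5 set in advance, and the test leaves the hypothesis open.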
